A study of Mus musculus with 12 samples.

How the data were processed

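The series measured gene expression in mouse cells with 12 Applied Biosystems 1-colour whole-genome arrays, each carrying 33012 probes. Per the labels, total RNA was extracted with Trizol and labelled with digoxigenin by a reverse transcription and in vitro transcription protocol. The labels give 4 groups of 3 arrays: ES cells, cultured epiblast (cEpi), and ES-like cells reprogrammed from epiblast (rEpiES) at passage 4 and at passage 24. Per the labels' protocols, the rEpiES cells were grown in serum with LIF on mitotically inactivated embryonic fibroblasts and were isolated from colonies in which an Oct4 reporter had become active. The culture of the cEpi cells is not described there. The same labels do not say whether the 3 arrays of a group came from separate cultures or lines. So p-values measure the spread between arrays, pooled over the 4 groups, which may be technical.

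The deposited file of each array holds a linear signal intensity per probe, for which no normalisation between arrays is stated and whose median differs between arrays. The scanner software and any background correction are not given in the sources used here. A further column holds, per the file headers, the authors' quantile-normalised values. They lie on a log2 scale, follow the rank order of the deposited intensity within each array, and values of the same rank differ by at most 0.0284 between the 12 arrays. These log2 values were the basis of the analysis. The deposited signal-to-noise score per probe was used to call detection at 3 or more. Other deposited columns hold quality codes whose meaning is not stated. In the files of cEpi and rEpiES passage 4 the headers of the score and of the code are exchanged relative to the contents, and numbers carry at most 1 decimal. In the files of ES and rEpiES passage 24 the headers match the contents. Columns were therefore read by their contents. These 2 file layouts each hold 2 groups, so rEpiES passage 4 minus cEpi and rEpiES passage 24 minus ES lie within a layout and the other 4 comparisons lie across layouts, where layout and group cannot be told apart. The value table of the whole series equals the authors' quantile-normalised column (largest difference 0), so it offered no separate alternative.

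Gene symbols came from a platform annotation table given with the data and were checked against a RefSeq gene table (assembly GRCm38.p6) by gene ID, which matched for 14402 of 14411 probes and changed 0 symbols. In all 14411 probes had 1 symbol, 247 had several and 18354 had none here. Chromosomes and the order of genes along them were taken from that gene table, and no coordinates are printed because no genome build is stated for the arrays. Nanog, Esrrb, Prdm14, T and Xist are not named in the annotation used here and have no values below.

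A probe was tested when it was detected on all 3 arrays of at least 1 group, which left 15235 probes, 9134 of them with 1 symbol and covering 8812 genes. Differences were tested with limma (lmFit and eBayes, two-sided) in a single fit of all 12 arrays without block or batch term, with 8 residual and 1.53 prior degrees of freedom. Probes with a Benjamini-Hochberg adjusted p under 0.05 were called. A change of 1 on the log2 scale is 2-fold. Changes are given as log2 change ± standard error, levels as mean ± SD over 3 arrays. Where a probe was detected on no array of the dimmer group, its fold is given as a bound ("at least"): the brighter group's mean over the dimmer group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own signal. This bound is no strict minimum. Some probes well above that lowest signal went undetected, such as Kat7 at 10.27 in ES. For many probes the bound equals the fitted fold, an estimate against background. The number of arrays per group limits the precision.

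The 26 gene lists were fixed before the data were examined: core pluripotency, naive pluripotency, post-implantation epiblast, primitive streak and mesendoderm, neural ectoderm, primitive and visceral endoderm, trophoblast, feeder fibroblast, germ cell, DNA methylation and histone modification, imprinted, LIF-STAT3, FGF-ERK, Nodal-Activin, BMP and WNT signalling, epithelial junction, mesenchymal, 2-cell-embryo, glycolysis and hypoxia, oxidative phosphorylation, stress response, p53 targets, Hox genes, sex chromosome, and haematopoietic and endothelial. Of their 458 distinct genes 364 had a named probe. For a gene with several probes the one with the highest mean over all arrays stood for it. Lists were tested with camera (limma, preset correlation 0.01, Benjamini-Hochberg over the 26 lists within a comparison). They were also tested with the correlation estimated from the data, and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. A list's spread is the SD over its members.

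The rule for named genes, fixed at the same time, took from each comparison the 10 largest rises and 10 largest falls among called probes with 1 symbol, detected on all 3 arrays of the higher group and without overlap between the arrays. Orders given here follow the fitted change, which for a probe not detected in the dimmer group is measured against background. The rule added called members of the fixed lists in order of absolute change, and Pou5f1, Sox2, Zfp42, Klf4, Dppa3, Fgf5, Otx2, Eomes, Cdh1 and Dnmt3b in every comparison. Their probes are, in this order, 615439, 848340, 916512, 440920, 893323, 783155, 908792, 584143, 925329 and 914927. Also named were 6 members of the fixed lists whose changes against ES run opposite ways at the 2 passages, though other genes do so too. Probes that part along the layouts or at passage 24 alone were named as well. All of these were chosen after their values were seen.

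Overall similarity was the mean Pearson correlation over the tested probes of a group's arrays with the ES arrays minus that with the cEpi arrays, with an exact permutation of the ES and cEpi labels (20 assignments, two-sided). A share of probes nearer ES was counted over the probes called between cEpi and ES. For comparison it was simulated for a group equal to cEpi, as was the share of probes called against cEpi in the direction of ES. The probe and list tests were tested on simulated data: with 200 of 15235 probes changed, between cEpi and ES 62% of the changes of 1 log2 and 98% of the changes of 4 log2 were recovered, with 10 false calls. Between the passages 68% and 100% were recovered, with 4 false calls. In this probe simulation few probes changed and each probe had the same spread in all 4 groups. In the data most probes were called between cEpi and ES, and the median SD was 0.24 in ES and 0.09 in cEpi. So these rates do not describe the real comparisons. A shifted list was called in 10 of 10 simulated runs between cEpi and ES over 8812 genes, with 0 of 250 tests of other lists called. Genes were drawn independently there and no other list was moved. So these runs do not show how the list test behaves where genes correlate or most of them change.

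The alternatives, also fixed then, were background correction with normexp (offset 50) before quantile normalisation, median scaling, the deposited signal without further normalisation, no detection filter, detection on all 12 arrays, a fit of only the groups compared, eBayes with trend and robust, array weights, the replicate number as a block, stricter thresholds, Spearman correlation, the mean over all probes of a gene in place of its brightest, other list tests, and leaving out each array in turn. Added after the data were seen were leaving out values with a quality code of 5000 or more, leaving out 99 probes that part along the layouts or on the passage 24 arrays alone, and distances between groups with the noise subtracted. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.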

Results

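Expression was measured on 12 arrays of mouse cells, 3 arrays for each of 4 groups. ES cells, the pluripotent cells of the pre-implantation embryo kept in culture, served as a reference state. cEpi cells were cultured epiblast of post-implantation embryos. rEpiES cells were ES-like cells obtained by reprogramming such epiblast, taken at passage 4 and at passage 24. The comparisons ask how the epiblast and ES states differ, and to which of them the reprogrammed cells lie nearer.

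Of 33012 probes, 12061 to 13827 were detected per ES array, 14329 to 15034 per rEpiES passage 4 array, 14422 to 15637 per rEpiES passage 24 array and 15726 to 16537 per cEpi array. The median signal before normalisation was 673 to 772 in ES, 673 to 695 in rEpiES passage 4, 666 to 713 in rEpiES passage 24 and 765 to 820 in cEpi. The median SD of the log2 values between the 3 arrays of a group was 0.24 in ES, 0.09 in cEpi, 0.10 in rEpiES passage 4 and 0.11 in rEpiES passage 24. The single fit pools these unequal spreads, so standard errors and calls also reflect groups outside a comparison. They can be too small for ES and too large for the other groups. Without ES replicate 3 the calls rose from 8583 to 9427 in passage 4 minus cEpi and from 5505 to 6661 between the passages. Every value below rests on n = 3 arrays per group. Some genes named below were detected on only part of a group's arrays. In ES these were Cer1, Gata1, Hoxa2 and 1 probe of Klf2 (1 of 3 arrays) and Bmp2, Car14, Dazl, Dnmt1, Pga5, Slc2a1, Slc2a3 and Ywhag (2 of 3). In cEpi they were Dnajc27 (1 of 3) and Dppa4, Nr5a2 and Tcf15 (2 of 3), at passage 4 Bmp2 and Foxc2 (1 of 3) and Dgke, Gata4, Msx1, Plac1 and Plcg1 (2 of 3), and at passage 24 Bmp2, Foxa2, Foxc2, Gata1, Hoxb2, Msx1, Pga5 and Sox17 (1 of 3) and Acta2, Pax6 and Snai1 (2 of 3). Of 15235 probes tested 12584 differed between at least some of the 4 groups (limma F test).

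A set of probes parted the groups along the 2 file layouts in which the arrays were deposited: 35 probes were brighter in both ES and rEpiES passage 24 than in both other groups by over 2 log2, among them the probes named Jak1, Olfr1238, Dgke, Colgalt2 and Plcg1. On the rEpiES passage 24 arrays alone, 41 probes were dimmer and 23 brighter than in the 3 other groups by over 3 log2, among them Ppp2ca, Sdhb and Dkk1 (dimmer) and Tfec, Enpep and Agr2 (brighter). At this gap the cEpi arrays alone had 50 dimmer and 30 brighter probes, the ES arrays alone 10 and 1, and the passage 4 arrays alone 0 and 0. At over 5 log2 the counts were 16 and 10 at passage 24, 0 and 1 in cEpi, 0 and 1 in ES and 0 and 0 at passage 4. At over 1 log2 they were 219 and 96 at passage 24, 486 and 769 in cEpi, 371 and 102 in ES and 6 and 13 at passage 4.

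The comparison of cEpi with ES set both reference states side by side. Naive pluripotency genes were lower in cEpi: Nr5a2, an orphan nuclear receptor, changed by -5.49 ± 0.25 on the log2 scale, Dppa3, a maternal-effect and germ-line factor, by -5.27 ± 0.14, and Zfp42, a zinc-finger marker of undifferentiated cells, by -4.10 ± 0.13. All 14 measured members of this list were lower by their brightest probe, also when adjusted over the list alone (14). For Klf2 the brightest probe changed by -0.41, but its other probe was called higher (2.43). That other probe was detected on 1 of 3 ES arrays. The naive pluripotency mean was -2.72 ± 1.58 (camera adjusted p = 5.63e-08, adjusted p = 0.00563 with an estimated correlation). Of 12 core pluripotency genes 1 was higher, 11 were lower and 0 were not called (1 higher and 11 lower adjusted over the list alone), led by Dppa2 (-4.72 ± 0.15), Foxd3, a forkhead factor that was higher (3.42 ± 0.38, at least 10.7-fold), and Dppa4 (-3.33 ± 0.15). This list had a mean of -1.20 ± 1.93 (adjusted p = 0.000162, adjusted p = 0.148 with an estimated correlation).

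Genes of endoderm were higher in cEpi. Among 12 primitive and visceral endoderm genes 10 were higher and 2 were not called (10 higher and 0 lower adjusted over the list alone), with Sox17 at 4.63 ± 0.36, Gata4 at 3.81 ± 0.37 (at least 14-fold) and Foxa1 at 3.17 ± 0.18 (at least 8.98-fold), all transcription factors of endoderm. The list mean was 2.04 ± 1.39 (adjusted p = 0.000935, adjusted p = 0.189 with an estimated correlation). Markers of feeder fibroblasts moved with them: of 22 genes 20 were higher and 2 were not called (20 higher and 0 lower adjusted over the list alone), led by the proteoglycan gene Bgn (5.04 ± 0.09) and Thy1 (4.70 ± 0.17, at least 26-fold). The feeder fibroblast mean was 2.28 ± 1.20 (adjusted p = 8.74e-07, adjusted p = 0.274 with an estimated correlation). All 12 mesenchymal genes were higher too (12 adjusted over the list alone), with Foxc2 at 3.40 ± 0.38 (at least 10.5-fold) and Zeb1 at 2.42 ± 0.26 (at least 5.34-fold). The mesenchymal list mean was 1.97 ± 0.66 (adjusted p = 0.000365, adjusted p = 0.189 with an estimated correlation). The mesenchymal list shares Cdh11 and Mmp2 with the feeder list and Sparc with the endoderm list.

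Of 19 DNA methylation and histone modification genes 4 were higher, 11 were lower and 4 were not called (4 higher and 11 lower adjusted over the list alone), the lowest being Dnmt3l (-4.65 ± 0.06), the cofactor of the de novo DNA methyltransferases, and Jarid2 (-1.97 ± 0.06). Their mean was -0.63 ± 1.27 (adjusted p = 0.0102, adjusted p = 0.277 with an estimated correlation). Of 22 glycolysis and hypoxia genes 16 were higher, 3 were lower and 3 were not called (16 higher and 3 lower adjusted over the list alone), with the glucose transporters Slc2a3 (5.62 ± 0.30) and Slc2a1 (3.92 ± 0.18) first. Their mean was 1.19 ± 1.84 (adjusted p = 0.036, adjusted p = 0.373 with an estimated correlation), and the call was lost with median scaling (adjusted p = 0.269), with no further normalisation (0.341), with detection on all 12 arrays (0.0666), with a fit of these 2 groups (0.06), without values of a high quality code (0.0828) and without ES replicate 2 (0.0521). Of 11 Hox genes, regulators of body-axis patterning, 9 were higher and 2 were not called (9 higher and 0 lower adjusted over the list alone), and the list was not called (adjusted p = 0.0544, adjusted p = 0.189 with an estimated correlation). It was called without a detection filter (adjusted p = 0.00869), with a fit of these 2 groups (0.0307), with the replicate number as a block (0.0424), and without rEpiES passage 4 replicate 2 (0.0448) or 3 (0.0475) or passage 24 replicate 1 (0.0482) or 2 (0.0423).

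Other large rises in cEpi were those of Asb4 (6.73 ± 0.35, at least 98.9-fold), Pga5 (6.61 ± 0.52), Cer1 (6.60 ± 0.47), which encodes a secreted antagonist of Nodal and BMP, and Pyy (5.92 ± 0.32, at least 60.7-fold), which encodes a gut hormone. Large falls were those of Olfr1238 (-7.45 ± 0.17, at least 175-fold) and Dgke (-6.49 ± 0.40, at least 90.1-fold), both among the probes that part along the layouts. Pou5f1 changed by -1.01 ± 0.13, Sox2 by -1.65 ± 0.08, Klf4 by -1.48 ± 0.07 and Dnmt3b by -1.40 ± 0.10. Fgf5, a growth factor of the post-implantation epiblast, changed by 1.55 ± 0.06, Otx2 by 0.54 ± 0.08 and Eomes by 1.40 ± 0.12. The post-implantation epiblast list, which holds Fgf5, Otx2 and Dnmt3b, was not called in this comparison. Cdh1, the gene of E-cadherin, changed by -0.24 ± 0.07, but by 0.22 with median scaling and 0.34 without further normalisation, where it was not called, nor was it without a detection filter (adjusted p = 0.107) or with a fit of these 2 groups (0.061). Pou5f1 was not called without further normalisation (-0.47, adjusted p = 0.083).

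In all 10091 probes were called, 5579 higher and 4512 lower in cEpi, and 3246 and 1891 of these changed at least 2-fold. Of the tested probes 1854 were detected on no ES array and 385 on no cEpi array. For these a change is measured against background, more often that of ES. Higher probes made up 55.3% of the calls, but 82.3% with median scaling and 86% without further normalisation, where the median of all probes shifted by 0.54 and 0.67 log2. The changes given are relative to the quantile-normalised distribution, and ES and cEpi lie in different file layouts.

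**Figure D1:**
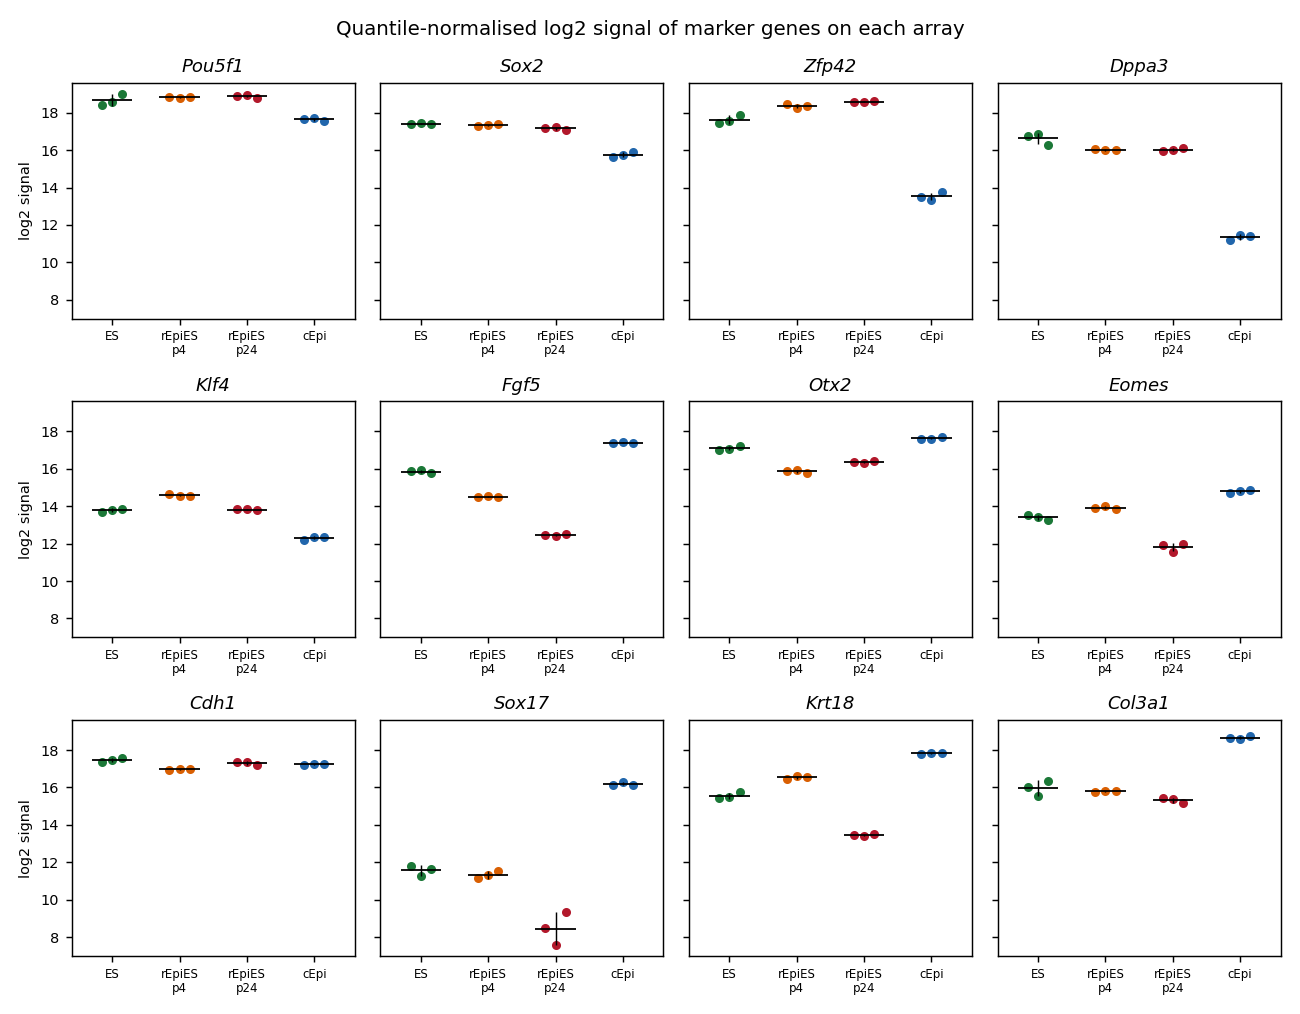
Quantile-normalised log2 signal (vertical axis) of 12 marker genes in the 4 groups (horizontal axis), with a point per array, a line at the mean and a bar for the SD over 3 arrays; p4 and p24 stand for passage 4 and passage 24. Zfp42 changed by -4.10 from ES to cEpi and by 4.83 from cEpi to rEpiES passage 4, and Krt18 by -3.10 from passage 4 to passage 24.

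The reprogrammed cells at passage 4 were compared with cEpi within the same file layout. Naive pluripotency genes were higher in rEpiES: Tcl1, a coactivator of Akt kinase, by 5.39 ± 0.13 (at least 42-fold), Zfp42 by 4.83 ± 0.13 and Dppa3 by 4.66 ± 0.14. All 14 list members were higher, also adjusted over the list alone (14). The naive pluripotency mean was 3.36 ± 1.25 (adjusted p = 6.55e-10, adjusted p = 0.00265 with an estimated correlation). Of 12 core pluripotency genes 8 were higher and 4 were not called (8 higher and 0 lower adjusted over the list alone), led by Dppa4 (4.69 ± 0.15) and Dppa2 (4.35 ± 0.15). The core pluripotency mean was 1.33 ± 1.60 (adjusted p = 0.00085, adjusted p = 0.13 with an estimated correlation). Of 11 germ cell genes 8 were higher, 1 was lower and 2 were not called (8 higher and 1 lower adjusted over the list alone), with Mael (4.71 ± 0.25, at least 26.2-fold) and Sycp1 (4.41 ± 0.94, at least 21.3-fold), genes of transposon silencing and of the synaptonemal complex. The germ cell mean was 1.95 ± 2.09 (adjusted p = 0.0413, adjusted p = 0.13 with an estimated correlation), and with detection on all 12 arrays it was -0.33 and not called (adjusted p = 0.977). Without values of a high quality code the germ cell call was lost as well (adjusted p = 0.0544).

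Primitive streak and endoderm genes were lower in rEpiES passage 4. Of 15 primitive streak and mesendoderm genes 12 were lower and 3 were not called (0 higher and 13 lower adjusted over the list alone), led by Cer1 (-5.11 ± 0.47), Lhx1 (-4.16 ± 0.38) and Foxa2 (-3.57 ± 0.32). The primitive streak mean was -2.03 ± 1.43 (adjusted p = 0.000384, adjusted p = 0.0794 with an estimated correlation). Of 12 endoderm genes 1 was higher, 9 were lower and 2 were not called (1 higher and 9 lower adjusted over the list alone), led by Sox17 (-4.87 ± 0.36) and Gata6 (-3.51 ± 0.19). The endoderm list mean was -1.46 ± 1.76 (adjusted p = 0.0112, adjusted p = 0.195 with an estimated correlation), and the call was lost with detection on all 12 arrays (adjusted p = 0.0877). Feeder fibroblast markers were lower as well: of 22 genes 18 were lower and 4 were not called (0 higher and 19 lower adjusted over the list alone), with the collagen genes Col5a2 (-2.94 ± 0.07) and Col3a1 (-2.86 ± 0.17) first. The feeder fibroblast mean was -1.80 ± 0.79 (adjusted p = 1.53e-08, adjusted p = 0.158 with an estimated correlation). Of 12 mesenchymal genes 11 were lower and 1 was not called (0 higher and 11 lower adjusted over the list alone), with Cdh2, the gene of N-cadherin, at -3.02 ± 0.08 and Foxc2 at -2.86 ± 0.38. The mesenchymal list mean was -1.62 ± 0.83 (adjusted p = 0.000192, adjusted p = 0.13 with an estimated correlation). Of 11 Hox genes 7 were lower and 4 were not called (0 higher and 7 lower adjusted over the list alone), led by Hoxb2 (-3.87 ± 0.14) and Hoxa2 (-2.57 ± 0.45, at least 5.95-fold). The Hox gene mean was -1.83 ± 0.95 (adjusted p = 0.0122, adjusted p = 0.13 with an estimated correlation).

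Among signalling lists, 13 LIF-STAT3 genes gave 0.62 ± 1.10 in the mean (adjusted p = 0.0435, adjusted p = 0.13 with an estimated correlation): 7 were higher, 1 was lower and 5 were not called (7 higher and 1 lower adjusted over the list alone), with the kinase genes Pim1 (2.97 ± 0.10) and Pim3 (2.57 ± 0.15) first. That call was lost with median scaling (adjusted p = 0.0534), without further normalisation (0.0785), with detection on all 12 arrays (0.0883), without rEpiES passage 24 replicate 1 (0.0508) and without the probes that follow the layout or passage 24 (0.0503), one of which is Jak1. Of 17 WNT genes 1 was higher, 8 were lower and 8 were not called (1 higher and 8 lower adjusted over the list alone), with the antagonists Dkk1 (-3.99 ± 0.09) and Sfrp1 (-3.18 ± 0.13) first. The WNT list mean was -0.82 ± 1.24 (adjusted p = 0.0426, adjusted p = 0.287 with an estimated correlation). The WNT call was lost without a detection filter (adjusted p = 0.0733), with detection on all 12 arrays (0.154), without rEpiES passage 4 replicate 2 (0.0533) and without the probes that follow the layout or passage 24 (0.0937), one of which is Dkk1.

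Other large rises at passage 4 were those of Septin1 (4.95 ± 0.11) and Fam25c (4.84 ± 0.22), and large falls those of Pyy (-5.31 ± 0.32, at least 39.7-fold), Cer1 and Gip (-4.90 ± 0.38, at least 27.4-fold). Pou5f1 changed by 1.17 ± 0.13, Sox2 by 1.57 ± 0.08 and Klf4 by 2.29 ± 0.07. Fgf5 changed by -2.89 ± 0.06, Otx2 by -1.79 ± 0.08, Eomes by -0.88 ± 0.12 and Dnmt3b by -0.66 ± 0.10. Cdh1 changed by -0.27 ± 0.07 and was not called without a detection filter (adjusted p = 0.0861). In all 8583 probes were called, 4299 higher and 4284 lower, with 1569 and 2026 at least 2-fold. The higher share of 50.1% was 31.5% with median scaling and 20.1% without further normalisation, where the median of all probes shifted by -0.23 and -0.44.

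At passage 24 the naive pluripotency genes were again higher than in cEpi, with Tcl1 at 5.44 ± 0.13 (at least 43.3-fold), Zfp42 at 5.06 ± 0.13 and Dppa3 at 4.67 ± 0.14. All 14 were higher, also adjusted over the list alone (14). The naive pluripotency mean was 3.20 ± 1.49 (adjusted p = 1.37e-07, adjusted p = 0.00763 with an estimated correlation). Of 12 core pluripotency genes 9 were higher, 1 was lower and 2 were not called (9 higher and 1 lower adjusted over the list alone), with Dppa4 at 5.45 ± 0.15 and Dppa2 at 4.81 ± 0.15. The core pluripotency mean was 1.42 ± 1.95 (adjusted p = 0.00413, adjusted p = 0.153 with an estimated correlation). Of 11 germ cell genes 9 were higher, 1 was lower and 1 was not called (9 higher and 1 lower adjusted over the list alone), led by Mael (4.99 ± 0.25, at least 31.8-fold) and Dazl (4.82 ± 0.46, at least 23.4-fold). The germ cell mean was 2.05 ± 2.15 (adjusted p = 0.042, adjusted p = 0.153 with an estimated correlation). The germ cell call was lost without ES replicate 1 (adjusted p = 0.0594) and with detection on all 12 arrays (0.987, mean -0.37). Of 19 DNA methylation and histone modification genes 13 were higher, 3 were lower and 3 were not called (14 higher and 3 lower adjusted over the list alone), led by Dnmt3l (4.68 ± 0.06) and Uhrf1 (2.17 ± 0.06), a factor of maintenance methylation. The DNA methylation list mean was 0.86 ± 1.21 (adjusted p = 0.00413, adjusted p = 0.188 with an estimated correlation).

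All 15 primitive streak and mesendoderm genes were lower at passage 24 than in cEpi (15 adjusted over the list alone), with Cer1 at -8.81 ± 0.47 (at least 445-fold), Lhx1 at -6.88 ± 0.38 (at least 118-fold) and Foxa2 at -6.10 ± 0.32. The primitive streak mean was -3.75 ± 2.11 (adjusted p = 1.09e-05, adjusted p = 0.0275 with an estimated correlation). Of 12 endoderm genes 1 was higher, 9 were lower and 2 were not called (1 higher and 9 lower adjusted over the list alone), with Sox17 at -7.74 ± 0.36 and Gata4 at -4.27 ± 0.37 (at least 15.8-fold). The endoderm list mean was -2.36 ± 2.32 (adjusted p = 0.00304, adjusted p = 0.153 with an estimated correlation). Feeder fibroblast markers moved the same way: of 22 genes 19 were lower and 3 were not called (0 higher and 19 lower adjusted over the list alone), led by Acta2 (-4.25 ± 0.21) and Col5a2 (-3.96 ± 0.07). The feeder fibroblast mean was -2.55 ± 1.10 (adjusted p = 7.42e-08, adjusted p = 0.153 with an estimated correlation). All 12 mesenchymal genes were lower (12 adjusted over the list alone), with Cdh2 at -4.79 ± 0.08. The mesenchymal list mean was -2.49 ± 0.98 (adjusted p = 2.92e-05, adjusted p = 0.153 with an estimated correlation). Of 11 Hox genes 7 were lower and 4 were not called (0 higher and 7 lower adjusted over the list alone), with Hoxb2 at -4.78 ± 0.14 and Hoxa2 at -2.84 ± 0.45 (at least 7.18-fold). The Hox gene mean was -1.87 ± 1.27 (adjusted p = 0.0276, adjusted p = 0.153 with an estimated correlation). Of 15 imprinted genes 2 were higher, 12 were lower and 1 was not called (2 higher and 12 lower adjusted over the list alone), with Phlda2 at -4.71 ± 0.11 and Gnas at -2.84 ± 0.08. The imprinted list mean was -1.27 ± 1.51 (adjusted p = 0.0131, adjusted p = 0.153 with an estimated correlation).

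Of 17 WNT genes 3 were higher, 12 were lower and 2 were not called (4 higher and 12 lower adjusted over the list alone), led by Dkk1 (-7.60 ± 0.09, at least 193-fold), which is among the probes dim at passage 24 alone, and Rspo3 (-4.81 ± 0.15, at least 28-fold). Their mean was -1.66 ± 2.20 (adjusted p = 0.0113, adjusted p = 0.188 with an estimated correlation), not called with detection on all 12 arrays (adjusted p = 0.204). Of 12 BMP genes 2 were higher, 8 were lower and 2 were not called (2 higher and 8 lower adjusted over the list alone), with Bmp2 at -4.29 ± 0.56 and Msx1 at -3.96 ± 0.59. The BMP list mean was -1.61 ± 1.96 (adjusted p = 0.0454, adjusted p = 0.164 with an estimated correlation). The BMP call was lost with median scaling (adjusted p = 0.0528), without further normalisation (0.0827), with detection on all 12 arrays (0.0946), with array weights (0.058), without ES replicate 2 (0.0686) and without rEpiES passage 24 replicate 3 (0.0653). Of 12 Nodal-Activin genes 2 were higher, 8 were lower and 2 were not called (2 higher and 9 lower adjusted over the list alone), with Cer1 and Furin (-2.87 ± 0.07) first. The Nodal-Activin list mean was -1.24 ± 2.70 (adjusted p = 0.0483, adjusted p = 0.276 with an estimated correlation). The Nodal-Activin call was lost with both scalings (adjusted p = 0.154 and 0.186), with detection on all 12 arrays (0.129), with a fit of these 2 groups (0.0762) and with array weights (0.0555). It was also lost without ES replicate 1 (0.0594) or 2 (0.0646), rEpiES passage 4 replicate 1 (0.0512) or 3 (0.0507), rEpiES passage 24 replicate 2 (0.0544) or cEpi replicate 2 (0.0526).

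Large changes at passage 24 were the rise of Tfec (9.98 ± 0.37, at least 1007-fold) and the fall of Ppp2ca (-10.21 ± 0.08, at least 1186-fold), the gene of a phosphatase catalytic subunit, both among the probes parted on these arrays alone. Pou5f1 changed by 1.23 ± 0.13, Sox2 by 1.40 ± 0.08 and Klf4 by 1.51 ± 0.07. Fgf5 changed by -4.94 ± 0.06, Otx2 by -1.28 ± 0.08 and Eomes by -2.98 ± 0.12. Cdh1 was not called (0.08 ± 0.07, adjusted p = 0.379). Dnmt3b changed by 0.39 ± 0.10, and was not called with median scaling (0.32, adjusted p = 0.132) or without further normalisation (0.13, 0.599). In all 10088 probes were called, 5071 higher and 5017 lower, with 2417 and 2952 at least 2-fold. The higher share of 50.3% was 39% with median scaling and 29.7% without further normalisation, with shifts of the median of -0.19 and -0.38. These groups lie in different file layouts.

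Against ES, rEpiES cells at passage 4 had higher levels of Klf2, a naive pluripotency factor, of Slc2a3 (5.16 ± 0.30) and of Ywhag (4.82 ± 0.36). Klf2 has several probes, at 6.47 ± 0.38 and, for the brightest, 2.96 ± 0.08. Large falls were those of Olfr1238 (-7.68 ± 0.17, at least 206-fold), Dgke (-6.32 ± 0.40) and Colgalt2 (-4.98 ± 0.14, at least 31.5-fold), all among the probes that part along the layouts, and these groups lie in different layouts. Of 14 naive pluripotency genes 8 were higher, 3 were lower and 3 were not called (8 higher and 3 lower adjusted over the list alone), with Tcl1 at 2.80 ± 0.13, and the list was not called (mean 0.64 ± 1.17, adjusted p = 0.45). Of 12 core pluripotency genes 3 were higher, 4 were lower and 5 were not called (3 higher and 4 lower adjusted over the list alone, adjusted p = 0.484). Of 15 primitive streak and mesendoderm genes 2 were higher, 8 were lower and 5 were not called (2 higher and 8 lower adjusted over the list alone). Their mean was -0.78 ± 1.11 and the list was not called (adjusted p = 0.158, adjusted p = 0.507 with an estimated correlation), but it was with median scaling (adjusted p = 0.00103), without further normalisation (0.00238) and with a fit of these 2 groups (0.043). Camera in the fit of all arrays called 0 of the 26 lists between these groups, with 3 at an unadjusted p under 0.05, while fry called 22.

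Feeder fibroblast markers between rEpiES passage 4 and ES had a mean of 0.48 ± 1.04 (7 were higher, 2 were lower and 13 were not called, adjusted p = 0.45), with Bgn at 3.13 ± 0.09 and Thy1 at 3.04 ± 0.17 (at least 8.25-fold). Zfp42 changed by 0.73 ± 0.13, Klf4 by 0.81 ± 0.07 and Dppa3 by -0.61 ± 0.14. Fgf5 changed by -1.34 ± 0.06, Otx2 by -1.25 ± 0.08, Eomes by 0.52 ± 0.12 and Dnmt3b by -2.06 ± 0.10. Cdh1 changed by -0.52 ± 0.07 and was not called with median scaling (-0.26, adjusted p = 0.215) or without further normalisation (-0.33, adjusted p = 0.172). Pou5f1 (0.16 ± 0.13, adjusted p = 0.354) and Sox2 (-0.08 ± 0.08, adjusted p = 0.438) were not called, but Pou5f1 was without ES replicate 3 (0.33, adjusted p = 0.00418). In all 8421 probes were called, 4458 higher and 3963 lower, with 2122 and 1037 at least 2-fold. The higher share of 52.9% was 80.5% with median scaling and 76.7% without further normalisation, with shifts of the median of 0.30 and 0.23.

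At passage 24, within the file layout of ES, primitive streak and mesendoderm genes were lower than in ES. Foxa2, a forkhead factor of endoderm and midline, changed by -5.24 ± 0.32, Mixl1 by -5.22 ± 0.14 and Lhx1 by -4.62 ± 0.38 (at least 24.5-fold). Of the 15 members 12 were lower and 3 were not called (0 higher and 12 lower adjusted over the list alone). The primitive streak mean was -2.50 ± 1.68 (adjusted p = 4.65e-05, adjusted p = 0.0601 with an estimated correlation). Of 22 glycolysis and hypoxia genes 15 were higher, 2 were lower and 5 were not called (16 higher and 2 lower adjusted over the list alone), led by Slc2a3 (5.54 ± 0.30) and Slc2a1 (4.38 ± 0.18). The glycolysis list mean was 1.26 ± 1.62 (adjusted p = 0.0114, adjusted p = 0.411 with an estimated correlation), not called with detection on all 12 arrays (adjusted p = 0.0608). The feeder fibroblast list was not called (mean -0.27 ± 1.25, adjusted p = 0.207): 5 were higher, 12 were lower and 5 were not called, with Tagln at -2.64 ± 0.07, Acta2 at -2.63 ± 0.21 and Bgn at 2.44 ± 0.09. The naive list was not called either (mean 0.48 ± 1.35, 7 were higher, 4 were lower and 3 were not called, adjusted p = 0.414).

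Large rises at passage 24 over ES were those of Tfec (10.30 ± 0.37, at least 1261-fold) and Dnajc27 (8.68 ± 0.45, at least 411-fold) and large falls those of Ppp2ca (-9.75 ± 0.08, at least 858-fold) and Sdhb (-7.31 ± 0.15), a subunit gene of succinate dehydrogenase, all parted on the passage 24 arrays alone. Zfp42 changed by 0.96 ± 0.13, Fgf5 by -3.39 ± 0.06, Eomes by -1.58 ± 0.12 and Dnmt3b by -1.01 ± 0.10. Dppa3 (-0.60 ± 0.14) and Otx2 (-0.75 ± 0.08) were called, but not with median scaling (adjusted p = 0.0928 and 0.0581) or without further normalisation (0.0619 and 0.0649). Sox2 changed by -0.25 ± 0.08, but by 0.13 with median scaling and 0.07 without further normalisation, where it was not called, nor was it without a detection filter (adjusted p = 0.121), with a fit of these 2 groups (0.0571), with array weights (0.137) or without rEpiES passage 24 replicate 3 (0.0697). Pou5f1 (0.22 ± 0.13, adjusted p = 0.189), Klf4 (0.03 ± 0.07, adjusted p = 0.76) and Cdh1 (-0.17 ± 0.07, adjusted p = 0.0727) were not called. Median scaling called Pou5f1 (0.57, adjusted p = 0.0335) and Klf4 (0.48, 0.0318), and Pou5f1 was also called with array weights (0.0464) and without ES replicate 3 (0.40, 0.00143). Cdh1 was called with detection on all 12 arrays (adjusted p = 0.0497), with trend and robust in eBayes (0.0427) and without ES replicate 1 (0.0345). In all 9089 probes were called, 4668 higher and 4421 lower, with 2412 and 1560 at least 2-fold. The higher share of 51.4% was 75.9% with median scaling and 73.1% without further normalisation, with shifts of the median of 0.33 and 0.27.

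**Figure D2:**
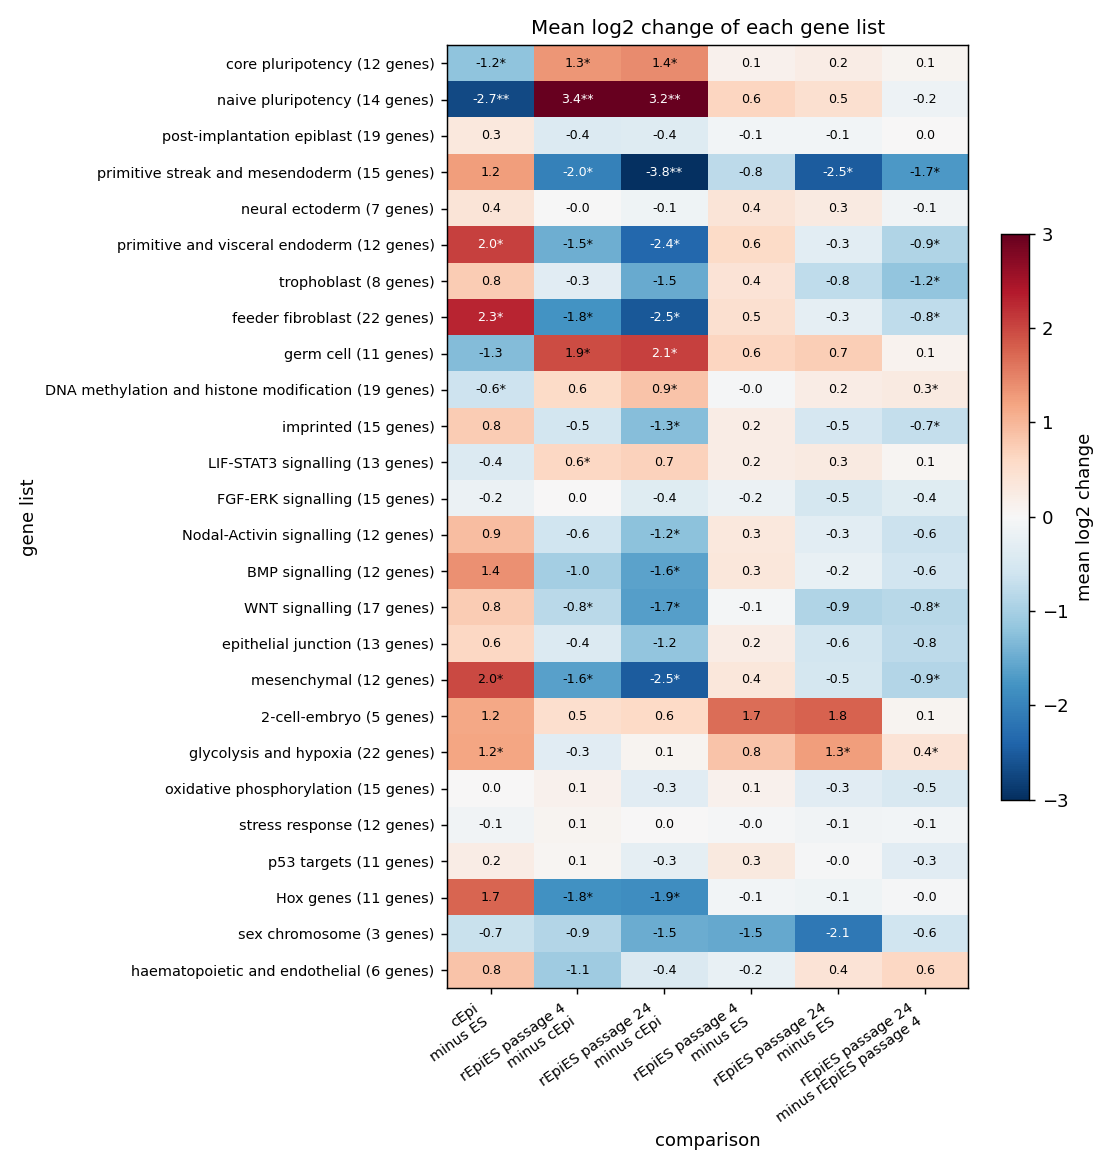
Mean log2 change (colour and number) of the 26 gene lists (vertical axis) in the 6 comparisons (horizontal axis); colours end at 3 in either direction, * marks lists called by camera with the preset correlation and ** those also called with an estimated correlation. The naive pluripotency list had means of -2.72 in cEpi minus ES, 3.36 in rEpiES passage 4 minus cEpi and 3.20 in rEpiES passage 24 minus cEpi.

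Between the passages, primitive streak, endoderm and trophoblast genes were lower at passage 24. Of 15 primitive streak and mesendoderm genes 10 were lower and 5 were not called (0 higher and 10 lower adjusted over the list alone), with Cer1 at -3.70 ± 0.47 (at least 12.9-fold), Sp5 at -3.39 ± 0.14 and Mixl1 at -3.01 ± 0.14. The primitive streak mean was -1.72 ± 1.26 (adjusted p = 4.48e-05, adjusted p = 0.0595 with an estimated correlation). Of 12 endoderm genes 7 were lower and 5 were not called (0 higher and 7 lower adjusted over the list alone), with Sox17 at -2.87 ± 0.36. The endoderm list mean was -0.90 ± 0.90 (adjusted p = 0.00156, adjusted p = 0.191 with an estimated correlation). Of 8 trophoblast genes 5 were lower and 3 were not called (0 higher and 5 lower adjusted over the list alone), with Plac1 at -2.29 ± 0.33 (at least 3.93-fold) and Krt7 at -2.29 ± 0.10. The trophoblast list mean was -1.18 ± 0.93 (adjusted p = 0.00857, adjusted p = 0.164 with an estimated correlation). Feeder fibroblast markers fell alongside: 2 were higher, 14 were lower and 6 were not called of 22 (2 higher and 15 lower adjusted over the list alone), with the smooth-muscle genes Tagln (-2.75 ± 0.07) and Acta2 (-2.24 ± 0.21) first, while Lum (1.17 ± 0.32) and Dcn (0.70 ± 0.14) were higher. Their mean was -0.75 ± 0.93 (adjusted p = 0.000194, adjusted p = 0.237 with an estimated correlation). Of 12 mesenchymal genes 8 were lower and 4 were not called (0 higher and 8 lower adjusted over the list alone), with Cdh2 at -1.77 ± 0.08 and Snai1 at -1.47 ± 0.25. The mesenchymal list mean was -0.87 ± 0.53 (adjusted p = 0.000568, adjusted p = 0.191 with an estimated correlation).

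Of 15 imprinted genes 1 was higher, 7 were lower and 7 were not called (1 higher and 7 lower adjusted over the list alone), led by Phlda2 (-3.07 ± 0.11) and Peg10 (-1.76 ± 0.13). The imprinted list mean was -0.72 ± 0.89 (adjusted p = 0.00681, adjusted p = 0.191 with an estimated correlation). Of 17 WNT genes 4 were higher, 9 were lower and 4 were not called (4 higher and 9 lower adjusted over the list alone), with Dkk1 (-3.61 ± 0.09, at least 12.2-fold) first and Sp5, shared with the streak list, next. The WNT list mean was -0.84 ± 1.43 (adjusted p = 0.0435, adjusted p = 0.237 with an estimated correlation). The WNT call was lost with array weights (adjusted p = 0.0786), with a fit of these 2 groups (0.0983), with detection on all 12 arrays (0.764), without the probes that follow the layout or passage 24 (0.104), and without ES replicate 2 (0.0659), ES replicate 3 (0.0746) or cEpi replicate 3 (0.0504). Of 19 DNA methylation and histone modification genes 8 were higher, 2 were lower and 9 were not called (10 higher and 2 lower adjusted over the list alone), with Uhrf1 at 1.42 ± 0.06 and Dnmt1 at -1.33 ± 0.21. The DNA methylation list mean was 0.28 ± 0.60 (adjusted p = 0.0149, adjusted p = 0.237 with an estimated correlation). Of 22 glycolysis and hypoxia genes 9 were higher, 2 were lower and 11 were not called (9 higher and 2 lower adjusted over the list alone), with Pfkp at 1.92 ± 0.48 and Egln3 at 1.65 ± 0.09. The glycolysis list mean was 0.41 ± 0.75 (adjusted p = 0.0149, adjusted p = 0.269 with an estimated correlation).

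Large changes between the passages were the rise of Tfec (10.09 ± 0.37, at least 1088-fold) and the fall of Ppp2ca (-10.05 ± 0.08, at least 1059-fold), both from probes parted at passage 24 alone, and these groups lie in different layouts. Klf4 changed by -0.78 ± 0.07, Fgf5 by -2.05 ± 0.06, Otx2 by 0.50 ± 0.08, Eomes by -2.10 ± 0.12 and Dnmt3b by 1.05 ± 0.10. Cdh1 changed by 0.35 ± 0.07 and was not called with median scaling (0.50, adjusted p = 0.0504), without further normalisation (0.51, 0.0786) or without a detection filter (0.35, 0.0538). Pou5f1 (0.06 ± 0.13, adjusted p = 0.753), Sox2 (-0.17 ± 0.08, adjusted p = 0.115), Zfp42 (0.23 ± 0.13, adjusted p = 0.192) and Dppa3 (0.01 ± 0.14, adjusted p = 0.977) were not called, except Zfp42 with a fit of these 2 groups (adjusted p = 0.047). In all 5505 probes were called, 2619 higher and 2886 lower, with 496 and 830 at least 2-fold. The count was 3498 with median scaling, 2912 without further normalisation and 7951 with array weights.

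**Figure D3:**
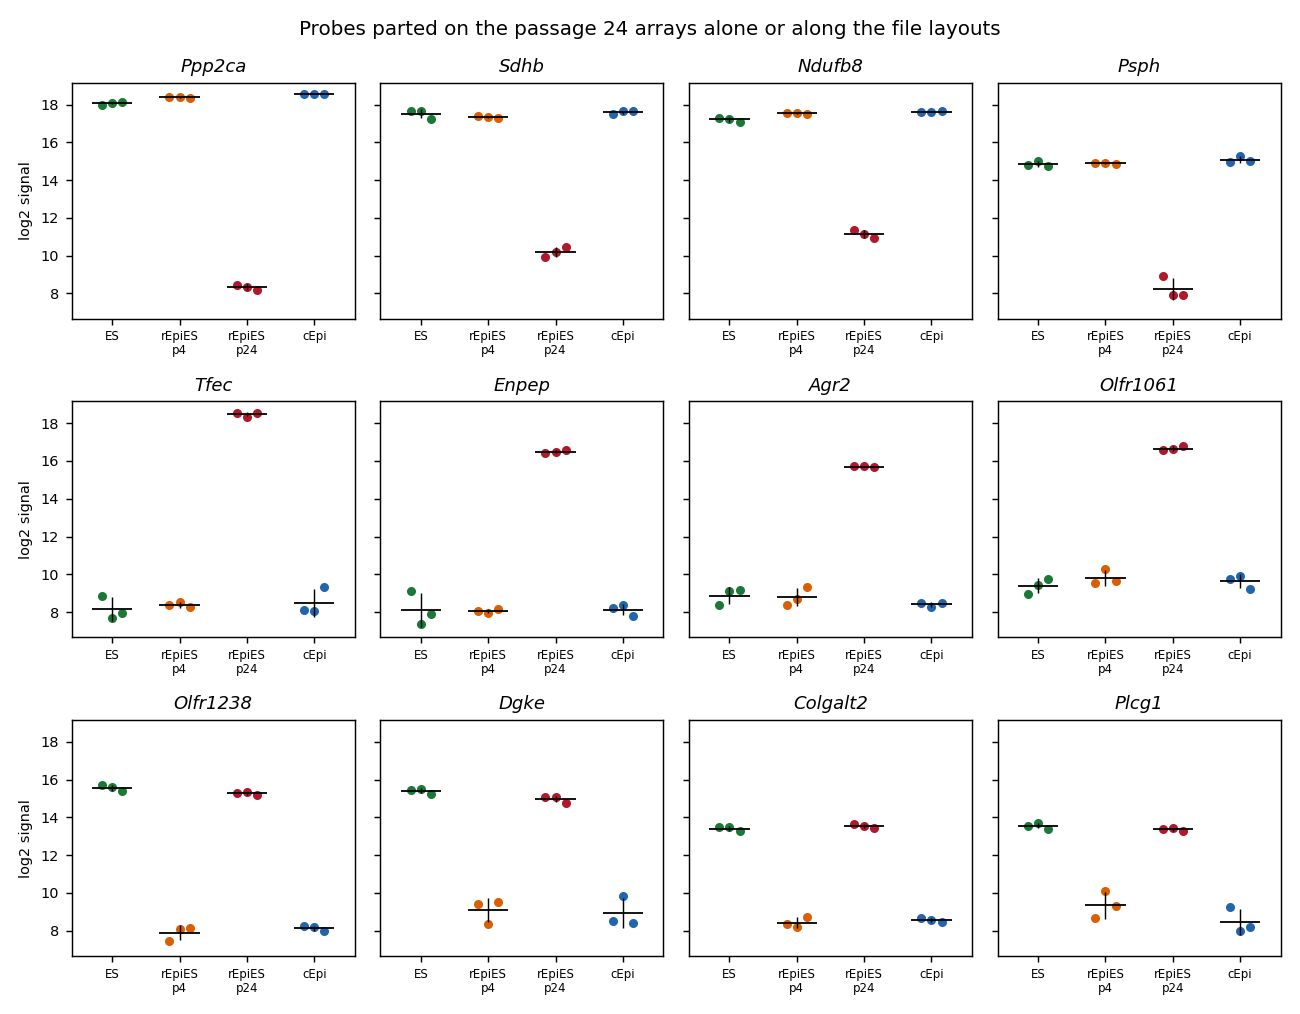
Quantile-normalised log2 signal (vertical axis) of 12 probes in the 4 groups (horizontal axis), with a point per array, a line at the mean and a bar for the SD over 3 arrays; p4 and p24 stand for passage 4 and passage 24. Ppp2ca lay at 8.34 ± 0.14 at passage 24 and 18.39 ± 0.03 at passage 4, Tfec at 18.47 ± 0.11 and 8.39 ± 0.15, and Olfr1238, which follows the file layout, at 15.27 ± 0.09 and 7.89 ± 0.39.

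The similarity of the reprogrammed cells to the reference states was measured over the 15235 tested probes, which are not independent replicates. rEpiES passage 4 arrays correlated at a mean r of 0.924 with ES and 0.913 with cEpi arrays, a difference of 0.0106 (SD 0.000235 over 3 arrays). rEpiES passage 24 arrays correlated at 0.901 with ES and 0.847 with cEpi, a difference of 0.0535 (SD 0.00105). For each passage the exact two-sided permutation p was 0.1, the smallest that 20 assignments allow. Without a detection filter the passage 4 difference was -0.0124 and that of passage 24 was 0.00558. The passage 4 difference was 0.00697 without ES replicate 3, 0.0231 with median scaling or without further normalisation, 0.0197 with detection on all 12 arrays, and 0.0181 with Spearman correlation. Arrays within a group correlated at 0.962 (ES), 0.994 (cEpi), 0.986 (passage 4) and 0.986 (passage 24), ES with cEpi at 0.881 and passage 4 with passage 24 at 0.944. Passage 24 shares its file layout with ES, so for its difference layout and cell state cannot be told apart. Passage 4 shares its layout with cEpi, and its difference lay towards ES, the group of the other layout. Without the 99 probes that part along the layouts or at passage 24 alone, an alternative chosen after the data were seen, the differences were 0.0157 and 0.0481. Root mean square log2 differences between group means, with the noise pooled over the 4 groups subtracted, were 0.908 between passage 4 and ES and 1.00 between passage 4 and cEpi, and 1.08 and 1.38 for passage 24.

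Among the 10091 probes called between cEpi and ES, 53% lay nearer ES than cEpi in rEpiES passage 4 and 59.7% in passage 24, against 2.44% in the mean of 20 simulations of a group equal to cEpi. That simulated group differs from cEpi by noise alone. So 2.44% is what no change from cEpi gives, not what a group unlike both references would give. Without ES replicate 3 the passage 4 share was 50.2%. The passage 24 share is open to the layout in the same way, while passage 4 and cEpi lie in the same layout. Without the 99 probes the shares were 53.2% and 59.5%. Over the 5137 probes that differed at least 2-fold these shares were 55.2% and 63.8%, against 1.62% simulated. Of the 1891 of these higher in ES, 77.4% were called against cEpi in the direction of ES at passage 4 and 82.8% at passage 24. Of the 3246 higher in cEpi, 56.9% and 63.6% were. Both comparisons use the same cEpi arrays. In the simulated groups equal to cEpi 0% were called in this direction, and 1.81% (passage 4) and 2.15% (passage 24) of the probes higher in ES and 2.32% and 2.79% of those higher in cEpi passed at the unadjusted p that the real calls reached (0.0282 and 0.0331). These simulated values do not tell a move towards ES from another difference from cEpi, which was not simulated.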

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

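The genes below were singled out after their values were seen, by a fixed rule, and the counts over other splits of the arrays were planned.

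The rule picked out 6 genes, all members of the fixed lists, whose changes against ES ran opposite ways at the 2 passages. They are not the only genes to do so. Among the probes dim at passage 24 alone, Rpl34 had means of 12.85 in ES, 13.95 at passage 4 and 9 at passage 24. Lage3 had means of 14.49, 15.42 and 8.45. Genes chosen this way differ between the passages by construction, so the differences below, from limma, restate the choice and are no separate test of it. Among the keratin genes, which encode intermediate filaments of epithelia, Krt8 was 0.82 against ES at passage 4 and -2.55 at passage 24, a difference of -3.37 ± 0.10 (adjusted p = 1.72e-08). Krt18 lay at 1.00 and -2.10, a difference of -3.10 ± 0.09 (adjusted p = 7.2e-09). Krt7 lay at 0.75 and -1.54, a difference of -2.29 ± 0.10 (adjusted p = 1.63e-07). Eomes, a T-box factor of mesendoderm and trophoblast, lay at 0.52 and -1.58, a difference of -2.10 ± 0.12 (adjusted p = 1.12e-06). Cer1 lay at 1.48 and -2.22, a difference of -3.70 ± 0.47 (at least 12.9-fold, adjusted p = 0.000252). But it was detected on 1 of 3 ES and 0 of 3 passage 24 arrays, so its change at passage 24 against ES lies near background and no fold is given for it. Plac1, a placental gene, lay at 1.22 (at least 2.32-fold) and -1.08, a difference of -2.29 ± 0.33 (at least 3.93-fold, adjusted p = 0.000556). It was detected on 0 ES, 0 passage 24 and 2 of 3 passage 4 arrays, so its value at passage 24 against ES compares levels at background and gives no fold. The call of Cer1 in passage 4 minus ES was lost without ES replicate 2 (1.21, adjusted p = 0.0765) and without passage 4 replicate 1 (0.0556), 2 (0.0513) or 3 (0.0563), and also with array weights (0.0613) and without a detection filter (0.0507). The call of Plac1 in passage 4 minus ES was lost without further normalisation (0.92, adjusted p = 0.0599), with a fit of these 2 groups (0.0656) and with array weights (0.0691). In passage 24 minus ES it was lost without ES replicate 1 (-0.81, adjusted p = 0.0653), with array weights (0.0681) and without passage 24 replicate 2 (-0.97, adjusted p = 0.0614). The 2 passages lie in different file layouts, so layout and passage cannot be told apart for these differences, and the changes at passage 4 against ES lie across layouts as well. No other explanation was tested for these genes.

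The counts of called probes were set against other splits of the same 6 arrays into 3 and 3. In each comparison 1 of 10 splits, the real one, gave as many calls. The real counts and the highest of the other splits were 10091 and 0 for cEpi minus ES, 8583 and 0 for rEpiES passage 4 minus cEpi, 10088 and 0 for rEpiES passage 24 minus cEpi, 8421 and 3 for passage 4 minus ES, 9089 and 4 for passage 24 minus ES, and 5505 and 0 between the passages. With 10 splits the share is never under 0.1. For the F test over 4 groups 1 of 100 drawn splits of the 12 arrays, the real one, gave as many as 12584 probes. This argues against a chance assignment of arrays to groups, at this number of splits. As the arrays of a group may be technical repeats, it does not exclude chance differences between single cultures. The highest other split gave 10351. A drawn split can keep arrays of a group together, and which arrays that split held was not examined.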

How the results depend on the processing

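The alternatives that leave out values with a quality code of 5000 or more, or the 99 probes that part along the layouts or at passage 24 alone, were chosen after the data were seen, and the others were planned. Of 704 pairs of a named gene and a comparison, 694 were called, and 618 of these kept direction and call in every alternative run while 76 lost the call in at least 1. Of 41 called pairs of a list and a comparison, 30 kept the call in every alternative except the estimated correlation, and of the pairs not called 15 were called in at least 1 alternative other than fry. A pair that an alternative could not test was counted as kept there, so 618 and 30 are upper limits. Detection on all 12 arrays tested 396 of the 704 gene pairs and 120 of the 156 list pairs. Leaving out the 99 probes tested 630 gene pairs. Normexp before quantile normalisation changed 0 of the 704 calls and 0 of 156 list calls, and the mean over all probes of a gene changed 0 list calls. Both had little room to differ from the main setting. Normexp keeps the rank order within an array, on which quantile normalisation rests, and the 9134 tested probes with 1 symbol cover 8812 genes. The series value table is identical to the values used and gave no separate result, and a layout term could not be estimated beside the groups and was not run. The cause of the changes below was not tested except where a stricter threshold or fewer probes make it plain.

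With median scaling 3498 probes were called between the passages, the similarity differences were 0.0231 (passage 4) and 0.0702 (passage 24), and the shares nearer ES were 52.6% and 56.7%. Without further normalisation these were 2912, 0.0231 and 0.0702, and the passage 4 share was 58.2%. Without a detection filter the similarity differences were -0.0124, a reversal, and 0.00558, and the shares 51.2% and 58.4%. With detection on all 12 arrays the differences were 0.0197 and 0.0548, and the passage 4 share 53.9%. Spearman correlation gave 0.0181 and 0.0662. Array weights raised the calls to 7951 between the passages, 10629 in passage 4 minus cEpi and 11784 in passage 24 minus cEpi. Leaving out values with a quality code of 5000 or more gave a passage 4 difference of 0.0109, and leaving out the 99 probes gave 0.0157 and 0.0481. Over probes with at least 2-fold differences the shares were 55.2% and 63.8%. Requiring a change of at least 1 log2 left 5137 (cEpi minus ES), 3595 (passage 4 minus cEpi), 5369 (passage 24 minus cEpi), 3159 (passage 4 minus ES), 3972 (passage 24 minus ES) and 1326 (between passages) calls, and an adjusted p under 0.01 left 3598 between passages. The estimated correlation left 4 list calls, and fry, which tests another question, made 134.

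Directions reversed for Cdh1 in cEpi minus ES (0.22 with median scaling, 0.34 without further normalisation), Olig2 in cEpi minus ES (0.083 and 0.21), Rlim in passage 24 minus ES (0.12 and 0.060) and Sox2 in passage 24 minus ES (0.13 and 0.074). Without further normalisation they also reversed for Rlim in cEpi minus ES (0.10) and passage 24 minus cEpi (-0.038) and for Eif1a in passage 4 minus cEpi (-0.068). With detection on all 12 arrays the mean of the germ cell list turned to -0.33 in passage 4 minus cEpi, where the test reversed too, and to -0.37 in passage 24 minus cEpi.

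Leaving out each array in turn gave 9096 to 10498 calls (cEpi minus ES), 7552 to 9427 (passage 4 minus cEpi), 9202 to 10691 (passage 24 minus cEpi), 7468 to 9023 (passage 4 minus ES), 8184 to 9576 (passage 24 minus ES), 4402 to 6661 (between passages), 11856 to 13031 for any difference and 37 to 44 list calls. The similarity difference ranged from 0.00697, without ES replicate 3, to 0.0132 at passage 4 and from 0.0509 to 0.0555 at passage 24, and the share from 50.2% to 53.8% and from 56.8% to 60.8%. Detection limits the dim side: between 36.5% and 50.1% of probes were detected per array.

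Replicate numbers did not pair the arrays: 18 same-number pairs had correlations of -0.0346 to 0.0373, 0 of them over 0.1, and 12 of 36 best matches followed the number. With a replicate block the calls were 9927, 8423, 9947, 8223, 8920 and 5164 in the order above, 12389 for any difference and 42 list calls, the additional one being the Hox genes in cEpi minus ES (adjusted p = 0.0424, 0.0544 without the block, 0.00869 to 0.219 over the other camera alternatives, and 1.81e-08 with fry, which asks another question).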

Other observations

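The tests of exchanged probe identities, of a batch along the file layout for the parted probes, of a segment of chromosome 11, and of Rpl34 and Plcg1 alone were chosen only after the results were seen. For the other tests of patterns noticed in these data, what each explanation requires was written before the value that decides it was seen.

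Of the 26 lists 16 were called in at least 1 comparison and 10 in none. In 21 pairs of a list and a comparison the mean or median had another sign than the test, 0 of them called. Among 13 epithelial junction genes 3 were higher, 7 were lower and 3 were not called from passage 4 to passage 24 (3 higher and 7 lower adjusted over the list alone), with Krt8 (-3.37 ± 0.10), Krt18 (-3.10 ± 0.09) and Krt19 (-2.47 ± 0.21) first. The list was not called there (adjusted p = 0.0551, adjusted p = 0.237 with an estimated correlation), but was with median scaling (adjusted p = 0.0288), without further normalisation (0.0256), without a detection filter (0.012), with detection on all 12 arrays (0.0451) and with trend and robust in eBayes (0.0409). It was also called without passage 4 replicate 1 (0.0448) or 3 (0.0421) and without passage 24 replicate 1 (0.0444) or 2 (0.0376). In passage 24 minus ES the junction list was not called (adjusted p = 0.0857, adjusted p = 0.411 with an estimated correlation), but was without a detection filter (0.0439). Among 15 FGF-ERK genes 3 were higher, 8 were lower and 4 were not called (4 higher and 8 lower adjusted over the list alone), with Fgf8 (-2.40 ± 0.12) and Fgf5 (-2.05 ± 0.06), and the list was not called (adjusted p = 0.0707, adjusted p = 0.237 with an estimated correlation), but was without a detection filter (adjusted p = 0.0487), with detection on all 12 arrays (0.0451) and with trend and robust (0.0412). Among 11 p53 targets 2 were higher, 6 were lower and 3 were not called (2 higher and 6 lower adjusted over the list alone), with Perp (-1.29 ± 0.10) and the cell cycle inhibitor Cdkn1a (-1.26 ± 0.07), and the list was not called (adjusted p = 0.057, adjusted p = 0.237 with an estimated correlation), but was under the same 3 settings (adjusted p = 0.0189, 0.0451 and 0.0412). Among 12 stress response genes 3 were higher, 6 were lower and 3 were not called (4 higher and 6 lower adjusted over the list alone, smallest list adjusted p = 0.445), with Chac1 at 1.93 ± 0.12 and Fos at -1.38 ± 0.08.

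In rEpiES passage 4 minus cEpi the post-implantation epiblast list had 19 members, of which 4 were higher, 9 were lower and 6 were not called (4 higher and 9 lower adjusted over the list alone), with Car14 (-3.45 ± 0.30), Fgf5 (-2.89 ± 0.06) and Tcf15 (2.31 ± 0.12), and its smallest value over the comparisons (adjusted p = 0.187). Of 15 oxidative phosphorylation genes 8 were higher, 3 were lower and 4 were not called there (8 higher and 3 lower adjusted over the list alone, adjusted p = 0.249), with Uqcrc1 at 0.86 ± 0.08, not called without further normalisation (0.45, adjusted p = 0.058). Of 6 haematopoietic and endothelial genes 1 was higher, 3 were lower and 2 were not called (1 higher and 3 lower adjusted over the list alone, adjusted p = 0.377), with Gata1 at -3.20 ± 0.36 (at least 8.73-fold). In rEpiES passage 24 minus ES 4 were higher and 1 was not called of 5 2-cell-embryo genes (4 higher and 0 lower adjusted over the list alone, adjusted p = 0.0936), with Tcstv3 at 4.09 ± 0.15 (at least 17-fold). Of 7 neural ectoderm genes 1 was higher and 6 were not called (1 higher and 0 lower adjusted over the list alone, adjusted p = 0.819), with Pax6 at 1.39 ± 0.34 (at least 2.62-fold). The sex chromosome list of 3 measured genes was not called there (adjusted p = 0.0803, adjusted p = 0.409 with an estimated correlation, 0 higher and 3 lower adjusted over the list alone), but was with median scaling (adjusted p = 0.023) and without further normalisation (0.0212).

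Y-linked probes were dimmer in the rEpiES groups: Eif2s3y, a translation factor gene, had means of 16.33 in ES, 15.53 in cEpi, 14.13 at passage 4 and 13.36 at passage 24, and Uty, a demethylase-family gene, 11.39, 10.70, 9.05 and 8.17, with detection on 0 rEpiES arrays. At passage 24 these 2 measured Y-linked genes changed by -2.97 ± 0.07 and -3.22 ± 0.42 (at least 9.32-fold) against ES, while X-linked Rlim, the third measured gene of the sex chromosome list, was at -0.25 ± 0.08 but 0.12 with median scaling and 0.060 without further normalisation. A difference along the file layout is argued against, as the smaller of the 2 median falls within a layout was -1.53, and so are cells with 2 active X chromosomes, as the X-linked median change against ES lay -0.105 from the autosomal median at passage 24 and 0.00376 at passage 4 (308 X-linked genes). A share of cells that lack a Y chromosome and have 1 active X may account for it, as a hypothesis. The values of 0.00376 and -0.105 met what was required of it. But cells with a Y chromosome and 1 active X would give such values too, so they do not decide whether the Y chromosome is absent. Which lines or sexes the arrays came from is not given in the sources used here, and a difference in origin of the lines stays open, as untested.

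The 41 probes dim and 23 bright at passage 24 alone fell or rose by over 3 log2 from the 3 other groups, as Ppp2ca, Sdhb and Tfec show, where cEpi alone had 50 and 30, ES alone 10 and 1 and passage 4 alone 0 and 0. Deletion of 1 chromosome segment is argued against for the set, as the 24 dim named probes lie on 14 chromosomes with at most 25% on 1 of them (6, on chromosome 11, where the share among named tested probes is 8.35%), with an upper limit of 46.7%, a condition on the limit added after the share was seen. A lost segment of chromosome 11 with at least 2 of these 6 is argued against too, as the 22 to 260 tested probes between neighbouring dim genes had median changes of -0.064 to 0.14. Exchanged probe identities stay open: 90.2% of the dim probes had a mirror partner among the bright, but so had 96% of those dim in cEpi alone, and the rule, which as first written counted this against the explanation, was changed after these values were seen because the control shows it to be saturated. Loss of the Rpl34 transcript is argued against, as its other tested probe changed by 0.34 ± 0.11 (SE) where the first changed by -4.40; for the other 23 dim named genes a loss in the cells, and for the bright probes a gain, possibly by passage, stays open: what was required was a median over other probes, and the 1 probe of Rpl34 cannot stand for genes that have no other tested probe.

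The 35 probes that part along the file layouts were brighter in ES and passage 24 than in the other groups, as Olfr1238 shows. At over 3 log2 they numbered 22, against 0 and 3 in the other pairings of the groups, a count that restates how they were noticed and decides nothing. For Plcg1 expression shared by ES and passage 24 cells is argued against, as its other tested probe differed by -0.58 ± 0.15 (SE) between the layouts where the first differed by 4.55. None of the other 7 named genes has another tested probe, and the 1 probe of Plcg1 cannot stand for them. For these, shared expression and a difference between array batches cannot be told apart, as each layout holds 2 whole groups.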
